A study of Homo sapiens with 12 samples.

How the data were processed

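Gene expression was measured by RNA sequencing in HT1080, an established human fibrosarcoma cell line. The labels place 12 libraries in 4 groups of 3: untreated cells, cells given IFNγ at 10 ng/ml, cells irradiated with 20 Gy, and cells given both. All were harvested after 24 h. IFNγ is the type II interferon, a cytokine that signals through JAK1 and JAK2. Per the labels' protocols, total RNA was purified on columns with DNase treatment, ribosomal RNA was removed, stranded total RNA libraries were made, and paired-end reads of 50 cycles were collected on an Illumina HiSeq instrument. The series' design text instead names an mRNA protocol, so whether poly(A) selection was used is unsettled.

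The authors deposited 1 table of raw counts per gene, which are whole-number counts with no normalization. Per the submitters' processing notes, FastQC 0.11.3, TopHat2 2.0.13, Cufflinks and Cuffdiff 2.2.1 were used with a human genome build of the hg19 generation. The counting tool, its strand setting and the annotation release are not given in the sources used here. Genes that overlap another gene, antisense genes and genes with near-identical copies (HLA genes, C4A and C4B, histones, globins) therefore carry counts of uncertain assignment. Of the table's 19293 gene identifiers, 90.1% matched GENCODE release 29, version number included, and 99.9% matched it at any version. That release is built on a different genome build from the named one, so no coordinates are given and the reference served only for the distance each gene spans.

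Every gene in the table is typed as protein coding. The column names over the first 4 columns are shifted by 1 place, and the columns were read by their content. A spreadsheet had turned 27 symbols into dates, and these genes were kept under their identifiers. Another 18 entries are pseudoautosomal Y copies, all with 0 counts. Each column of counts was matched to its library by the library's title, with 0 columns left unmatched. Total counts per library ran from 9675126 to 11010656. The filter left 12160 genes for testing, with a median of 324 counts per library, and the genes left out held 0.0678% of all counts.

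Counts were compared with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled with the trimmed mean of M-values (TMM), and all 12 libraries entered a single quasi-likelihood fit with robust dispersion estimates. The common biological coefficient of variation was 2.71%. Each contrast used the quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Contrasts were IFNγ against untreated, radiation against untreated, the combination against each of the other groups, and the interaction. The interaction is the log2 effect of IFNγ in irradiated cells minus its effect in unirradiated cells. Standard errors are the absolute log2 fold change divided by the square root of F. This quotient is an approximation. For genes with large fold changes, such as IRF1 and CIITA, its values do not match each other across contrasts and may be too small. Levels are given as CPM (counts per 1e6 counts of the TMM-scaled library total), as mean ± SD of 3 libraries.

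A group with 0 counts gives no fold change, so the ratio was computed against a floor of 3 counts over the group and is written as at least that many fold. With 1 to 3 counts in a group the ratio of counts is given with its exact 95% interval. Floors and intervals cover counting error only. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No library was a copy of another: over genes with at least 20 counts, chi-square per degree of freedom of the 12 replicate pairs ran from 1.13 to 2.67.

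The groups, the tests, 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment ran over the 26 lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. In 17 of the 156 list results the median, mean and test differed in sign, and 0 of these were called. Medians of lists in the main pairwise comparisons are given with genes at 0 counts placed at their floor. Medians of interaction terms, of alternative fits and over genes pooled from several lists use fitted values. These can include genes with few or 0 counts in a group. For each list the number of called members is given after adjustment over all genes tested and then adjusted over the list alone.

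Named genes are of 4 kinds. In each pairwise comparison they are the 6 called genes with the largest positive and the 6 with the largest negative log2 fold change, among genes with a mean log2 CPM of at least 2 and no overlap between the libraries of the compared groups. For the interaction they are the 6 largest called terms in each direction at the same mean. For a described list they are 2 to 4 of its 4 called members with the largest change, with called members of the opposite direction ranked separately. The remaining 25 were fixed by name, and results of some genes are not reported here. Genes outside this rule are named in the closing section only where it says so, or where a count is small.

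Alternatives were size factors from DESeq2, library totals without TMM, TMM without the 10 most abundant and the mitochondrial genes, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, fits of the compared groups only, the replicate number as a block, an adjusted p under 0.01, and each library left out in turn. Subtraction of an estimated carry-over of IFNγ-type reads was added after the data were seen, as were counts of list members without irradiated replicate 2. The subtraction used 11 marker genes with a log2 fold change of at least 8 in IFNγ against untreated. Lists of IFNγ and radiation effects were compared between contrasts that share no library.

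The procedure was tested on simulated counts with 200 changed genes, far fewer than the real pairwise comparisons called. The recovered shares below hold for that setting. For IFNγ against untreated, 40% of changes of 0.25 in log2 were recovered, 80% of changes of 0.5, 96% of changes of 1 and 100% of changes of 2, and 5.39% of calls were false. For the interaction the recovered shares were 24%, 66%, 86% and 98%, and 4.2% of calls were false. A simulated carry-over of 0.5% was found as 0.504%.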

Results

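The transcriptome of HT1080 fibrosarcoma cells was profiled 24 h after IFNγ (10 ng/ml), radiation (20 Gy), both, or neither, with 3 libraries per group. Total counts per library ran from 9762772 to 10550510 in untreated, 10263803 to 11010656 in IFNγ-treated, 9675126 to 10084853 in irradiated and 10254314 to 10956421 in combination cells. The first principal component, which held 45.5% of the variance, separated libraries with IFNγ from those without it. The second, with 39.8%, separated irradiated from unirradiated libraries. The table holds 8 of 13 listed mitochondrially encoded transcripts, and these 8 made up 3.58% ± 0.0462 (SD, n = 3) of counts in untreated, 3.51% ± 0.13 in IFNγ-treated, 4.45% ± 0.0115 in irradiated and 4.29% ± 0.0451 in combination libraries.

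The comparison of IFNγ with untreated cells asked what the cytokine did without radiation. Genes of antigen presentation, interferon signalling and antiviral defence rose, many of them from near silence. IDO1, which starts tryptophan breakdown, went from 0 counts to 181 ± 50.6 CPM (SD, n = 3), at least 1880-fold higher. APOL4 was at least 248-fold higher, HLA-DOA at least 106-fold, complement C4B at least 92-fold, and CXCL9, a chemokine that attracts T cells, at least 80.6-fold. GBP5, an interferon-inducible GTPase, rose by 10.36 ± 0.46 (log2 fold change ± SE) to 905 ± 152 CPM, and by 11.19 without untreated replicate 3.

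Decreases were smaller. HHIP, which binds Hedgehog ligands, fell from 341 ± 14.8 to 128 ± 16.5 CPM, a log2 fold change of -1.42 ± 0.092. MTURN (-1.5 ± 0.198), LRRC17 (-1.42 ± 0.158) and the adenylate kinase AK5 (-1.36 ± 0.181) fell. RFLNB fell by 1.34 ± 0.0607 and ST8SIA1, which makes the ganglioside GD3, fell by 1.26 ± 0.213. As the rule for named genes requires, the 3 IFNγ libraries lay on the same side of the 3 untreated libraries for each of these 12 genes.

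All 22 tested genes of MHC class I antigen presentation rose (22 adjusted over the list alone), led by the peptide transporter TAP1 (5.03 ± 0.122), the immunoproteasome subunit PSMB9 (4.91 ± 0.0767) and HLA-B (4.82 ± 0.111). The light chain B2M rose by 2.16 ± 0.0294. All 15 genes of MHC class II presentation rose (15 adjusted over the list alone), with a median log2 fold change of 5.11. CD74, the invariant chain, rose by 7.93 ± 0.296, and the class II transactivator CIITA by 5.05 ± 0.101. Reads of HLA genes can be shared between near-identical copies.

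Of 22 genes of IFNγ signalling, 18 rose and 0 fell (18 and 0 adjusted over the list alone), among them the transcription factors BATF2 (5.49 ± 0.179) and IRF1 (4.81 ± 0.169). JAK2 rose by 0.63 ± 0.12. IFNGR1 (-0.15 ± 0.076), IFNGR2 (-0.07 ± 0.0628) and JAK1 (0.07 ± 0.0373) were not called. Of 17 guanylate binding proteins and IFNγ effectors, 16 rose (16 adjusted over the list alone), including GBP4 (8.73 ± 0.411) and APOL3 (6.06 ± 0.139). Of 32 antiviral genes, 31 rose (31 adjusted over the list alone), including BST2, which tethers budding viruses, at 8.47 ± 0.217. Of 13 nucleic acid sensing genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone): the DNA sensor AIM2 rose by 4.41 ± 0.0995 and TLR3 by 3.23 ± 0.136, and the adaptor MAVS fell by 0.14 ± 0.0434.

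Among 15 chemokines and cytokines, 9 rose and 3 fell (9 and 3 adjusted over the list alone). CXCL10 was at least 34.7-fold higher and IL32 rose by 3.58 ± 0.226, whereas IL1A (-1.12 ± 0.206) and the neutrophil attractant CXCL8 (-1.10 ± 0.0788) fell. IL6 rose by 1.22 ± 0.278. Among 19 checkpoint, adhesion and death ligand genes, 11 rose and 3 fell (11 and 4 adjusted over the list alone). The adhesion molecule ICAM1 rose by 6.78 ± 0.382, the interleukin 18 inhibitor IL18BP by 4.66 ± 0.271, and CD274, which encodes PD-L1, by 0.73 ± 0.0688. Among 23 caspases and cell death effectors, 12 rose and 1 fell (13 and 4 adjusted over the list alone), with CASP1 (3.47 ± 0.113), CASP4 (1.43 ± 0.0509) and the pore-forming GSDMD (1.33 ± 0.0757) higher and BCL2 (-0.51 ± 0.102) lower.

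Extracellular matrix genes fell, with 20 of 29 lower and 3 higher (20 and 3 adjusted over the list alone). COL1A1 fell by 1.20 ± 0.187 and CTGF by 1.02 ± 0.0419 on the log2 scale, while tenascin TNC rose by 1.83 ± 0.07. The list's call was lost with an estimated correlation (adjusted p = 0.0569 with an estimated correlation). DNA replication genes rose slightly, 14 of 40 with 1 lower (14 and 1 adjusted over the list alone), led by RRM2 (0.26 ± 0.0312) and UHRF1 (0.20 ± 0.0431), with GINS4 at -0.23 ± 0.0694. This list had an adjusted p = 0.113 with an estimated correlation. Of 33 DNA break repair genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), led by NBN (0.64 ± 0.0393) and BRCA2 (0.39 ± 0.0565). ATM (0.10 ± 0.0467) was not called.

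The cystine transporter chain SLC7A11, which imports cystine for glutathione synthesis, fell from 108 ± 9.78 to 78.3 ± 6 CPM (SD, n = 3), a log2 fold change of -0.46 ± 0.0574 with an adjusted p of 2.51e-08. Its partner SLC3A2 was at -0.12 ± 0.0405, GPX4, which reduces lipid peroxides, at -0.29 ± 0.0515, and ACSL4, which activates polyunsaturated fatty acids, at 0.12 ± 0.0439. The cell cycle inhibitor CDKN1A fell by 0.31 ± 0.0444 and GDF15 by 0.14 ± 0.0503. MKI67 was at 0.11 ± 0.0281. MDM2 (0.06 ± 0.0342) and CCNB1 (0.05 ± 0.0337) were not called. IFNB1 had 0 counts in both groups. The calls of SLC3A2, ACSL4 and GDF15 ended in DESeq2, with adjusted p of 0.109, 0.107 and 0.0573. They also ended when untreated replicate 1 (log2 fold changes -0.09, 0.06 and -0.09) or IFNγ replicate 3 (-0.09, 0.09 and -0.11) was left out. That of ACSL4 further ended without untreated replicate 3 (0.13) or IFNγ replicate 2 (0.11).

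The lists of cystine import and glutathione (4 higher and 5 lower of 22), lipid peroxidation and iron (6 and 5 of 25), ATF4 and amino acid response (7 and 6 of 29), p53 targets (4 and 12 of 36), mitosis (7 and 0 of 34), NRF2 targets (5 and 8 of 27), cholesterol synthesis (3 and 5 of 25) and NF-κB targets (6 and 4 of 20) were not called. Adjusted over the list alone, these counts were 4 and 5, 6 and 5, 7 and 6, 5 and 14, 6 and 0, 5 and 10, 3 and 5, and 6 and 4. Replication-dependent histones (2 higher of 19), mitochondrial transcripts (2 of 8), ribosomal proteins (4 of 40), immune cell markers (1 of 3) and epithelial and endothelial markers (0 of 5) were not called either and had 0 genes lower. Ribosomal proteins were called without untreated replicate 1 (adjusted p = 0.0036) or IFNγ replicate 3 (adjusted p = 0.00595), and histones without IFNγ replicate 1 (adjusted p = 0.0474). Adjusted over the list alone they had 1, 2, 4, 1 and 0 genes higher. Of 16 reference genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone) with an adjusted p = 0.133 with an estimated correlation. B2M led this list, and its median of 0.05 became -0.005 without TMM.

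In total 3544 of 12160 genes were called (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 1829 higher and 1715 lower. At least 2-fold, 310 were higher and 74 lower. The share of called genes that were higher was 51.6%, and 31.1% with library totals in place of TMM. Of 26 lists 13 were called, and 10 with an estimated correlation. Camera on ranks also called 13, without the chemokine and checkpoint lists and with histones and ribosomal proteins.

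**Figure D1:**
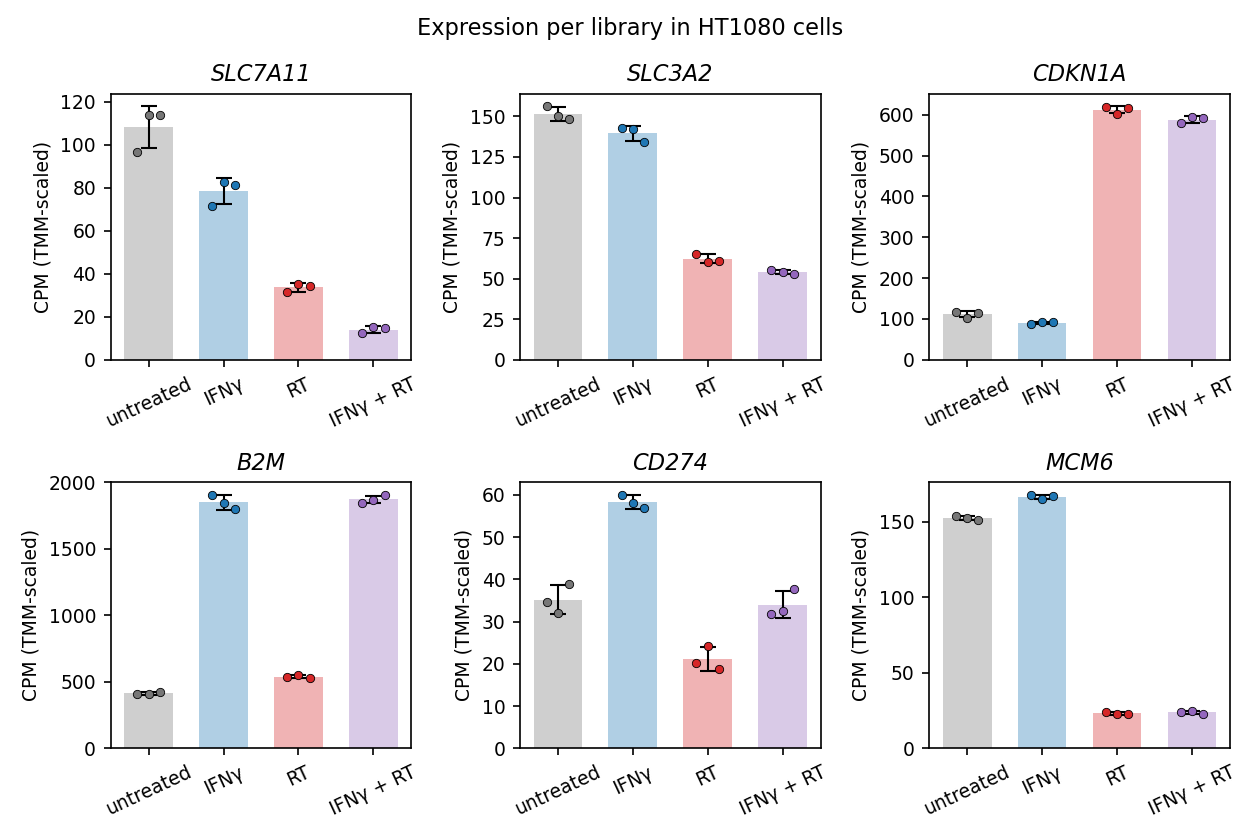
Levels (CPM) of SLC7A11, SLC3A2, CDKN1A, B2M, CD274 and MCM6 in each library (points) of the 4 groups, with bars at the group mean and error bars of 1 SD (n = 3). SLC7A11 stood at 108 CPM in untreated, 78.3 in IFNγ-treated, 33.6 in irradiated and 14.1 in combination cells.

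The comparison of irradiated with untreated cells asked what radiation did without IFNγ. Targets of p53 rose and genes of DNA replication and of the amino acid response fell. All 36 tested p53 targets were higher (36 adjusted over the list alone), with a median log2 fold change of 1.31. The ferredoxin reductase FDXR rose by 2.63 ± 0.073 (SE, n = 3), BTG2 by 2.44 ± 0.0736, and the cell cycle inhibitor CDKN1A from 112 ± 8.12 to 612 ± 8.77 CPM (SD, n = 3). The ubiquitin ligase MDM2 rose by 2.14 ± 0.0326 and the secreted GDF15 by 2.40 ± 0.0417.

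Of 40 DNA replication genes, 37 fell and 1 rose (37 and 1 adjusted over the list alone). The helicase subunit MCM6 fell from 152 ± 1.5 to 23.1 ± 0.936 CPM, a log2 fold change of -2.72 ± 0.053. The transcription factors E2F2 (-2.39 ± 0.186) and E2F1 (-2.30 ± 0.0899) fell, and the sliding clamp PCNA rose by 0.47 ± 0.0336. Of 33 DNA break repair genes, 20 fell and 3 rose (20 and 3 adjusted over the list alone). The nuclease EXO1 fell by 1.00 ± 0.0624 on the log2 scale, while the damage kinases ATM (0.43 ± 0.0455) and CHEK2 (0.32 ± 0.0852) rose. Mitotic genes went both ways, 11 higher and 15 lower of 34 (12 and 15 adjusted over the list alone), and the list was not called. HMMR (0.45 ± 0.0408) and CDK1 (0.37 ± 0.0414) rose, MKI67 (-0.57 ± 0.0287) and CDC20 (-0.49 ± 0.0346) fell, and CCNB1 (-0.002 ± 0.0338) was not called.

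Of 29 genes of the ATF4 and amino acid response, 23 fell and 3 rose (23 and 3 adjusted over the list alone). CHAC1, which degrades glutathione, fell from 7.64 ± 0.68 to 0.631 ± 0.356 CPM (-3.58 ± 0.256), and the neutral amino acid carrier SLC1A4 (-2.13 ± 0.131) and asparagine synthetase ASNS (-2.13 ± 0.059) fell. ATF3 rose by 1.00 ± 0.133. SLC7A11 fell to 33.6 ± 2.03 CPM, a log2 fold change of -1.68 ± 0.0666, and SLC3A2 to 62.2 ± 2.68 CPM, -1.28 ± 0.0456. GPX4 rose by 0.20 ± 0.049 and ACSL4 fell by 0.15 ± 0.0449, a call that ended when untreated replicate 2 was left out (-0.10). The wider lists of cystine import and glutathione (6 higher and 11 lower of 22), lipid peroxidation and iron (9 and 7 of 25), NRF2 targets (10 and 10 of 27) and cholesterol synthesis (7 and 12 of 25) were not called. Adjusted over the list alone they counted 6 and 12, 9 and 9, 11 and 10, and 7 and 12.

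NECTIN4, a cell adhesion molecule, rose from 4.45 ± 0.641 to 46.6 ± 1.42 CPM (3.38 ± 0.0979), MEGF6 by 3.29 ± 0.198 and HRNR by 2.97 ± 0.178. CEACAM1 rose from 3 counts over the untreated libraries, a ratio of 21.7 (95% interval 7.09 to 108). LGALS9 and CD5L had 1 count each in untreated cells, with ratios of 14.5 (2.2 to 611) and 12.4 (1.83 to 529). FAM111B (-3.31 ± 0.0925), the linker histone H1F0 (-2.81 ± 0.0484) and WDR76 (-2.50 ± 0.0894) fell. Extracellular matrix genes rose in 21 and fell in 4 of 29 cases (22 and 4 adjusted over the list alone), with ACTA2 (2.38 ± 0.0916) and BGN (2.27 ± 0.435) higher and CYR61 (-0.50 ± 0.0331) lower. This list had an adjusted p = 0.261 with an estimated correlation. All 8 mitochondrial transcripts were higher (8 adjusted over the list alone), led by MT-ND5 (0.44 ± 0.0314) and MT-ND6 (0.42 ± 0.0465), with an adjusted p = 0.278 with an estimated correlation.

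Some interferon-related genes were also higher in irradiated cells, by less than after IFNγ. Of 108 tested genes of 5 interferon lists, 45 were called higher, 4 lower and 59 not called. Over all 12160 tested genes, 3389 were called higher and 3427 lower. The 3 lists called here, given next, lost their calls with an estimated correlation. Of 22 genes of IFNγ signalling 12 rose (12 adjusted over the list alone), among them TRIM22 (1.94 ± 0.0721), STAT3 (0.95 ± 0.0456) and STAT2 (0.80 ± 0.0816). JAK1 rose by 0.27 ± 0.0368, and IRF1 (0.34 ± 0.315), JAK2 (-0.13 ± 0.135), IFNGR1 (0.13 ± 0.0733), IFNGR2 (0.04 ± 0.0621) and CIITA (-0.34 ± 0.227) were not called. Of 22 MHC class I genes 15 rose and 1 fell (15 and 1 adjusted over the list alone), with TAP1 (0.96 ± 0.184) and HLA-B (0.88 ± 0.174) higher and TAP2 (-0.23 ± 0.0504) lower. B2M rose by 0.38 ± 0.03. Of 32 antiviral genes 10 rose and 3 fell (9 and 2 adjusted over the list alone), with IFIT1 (1.5 ± 0.317) and IFI27 (1.21 ± 0.312) higher and CMPK2 (-0.52 ± 0.219) lower. The 3 lists had adjusted p = 0.278, 0.278 and 0.565 with an estimated correlation.

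Irradiated replicate 2 held more reads of genes that are near silent without IFNγ than the other libraries of its kind: 59 counts of GBP5 against 10 and 3, and 8 of IDO1 against 1 and 1. Without this library, 12 of 22 signalling genes, 14 of 22 MHC class I genes and 8 of 32 antiviral genes were higher, and 0, 1 and 2 were lower. Guanylate binding proteins and effectors (5 higher and 0 lower of 17, and 5 and 1 without irradiated replicate 2, with the median going from 0.56 to 0.13), MHC class II (3 and 0 of 15, and 1 and 1 without it) and nucleic acid sensing (6 and 3 of 13, and 5 and 3 without it) were not called as lists. The guanylate list was called without irradiated replicate 3 (adjusted p = 0.0466). Neither were chemokines and cytokines (6 and 2 of 15) or checkpoint, adhesion and death ligands (6 and 2 of 19). Adjusted over the list alone these had 5 and 0, 1 and 0, 6 and 3, 6 and 2, and 6 and 2. IL32 (2.48 ± 0.274) and IL6 (1.53 ± 0.266) rose and CXCL8 fell by 1.60 ± 0.0847. TNFRSF14, the herpesvirus entry mediator, rose by 2.17 ± 0.15 and CD274 fell by 0.74 ± 0.084. IFNB1 and CXCL10 had 0 counts in both groups. CXCL9 had counts within the floor, and IDO1, with counts of 1, 8 and 1 in irradiated and 0 in untreated libraries, was not called.

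Of 19 histone genes 10 rose and 3 fell (10 and 3 adjusted over the list alone), NF-κB targets counted 7 higher and 5 lower of 20 (7 and 5 adjusted over the list alone) and caspases and death effectors 7 and 6 of 23 (7 and 6 adjusted over the list alone). None of these lists was called, nor were ribosomal proteins (11 and 4 of 40), reference genes (4 and 10 of 16), immune cell markers (3 and 0 of 3) or epithelial and endothelial markers (2 and 0 of 5). Reference genes were called as lower without untreated replicate 2 (adjusted p = 0.0389). Adjusted over the list alone the last 4 counted 8 and 4, 4 and 10, 3 and 0, and 2 and 0. In total 6816 genes were called (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 3389 higher and 3427 lower, with 470 higher and 141 lower by at least 2-fold. Of 26 lists 9 were called, and 4 with an estimated correlation.

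**Figure D2:**
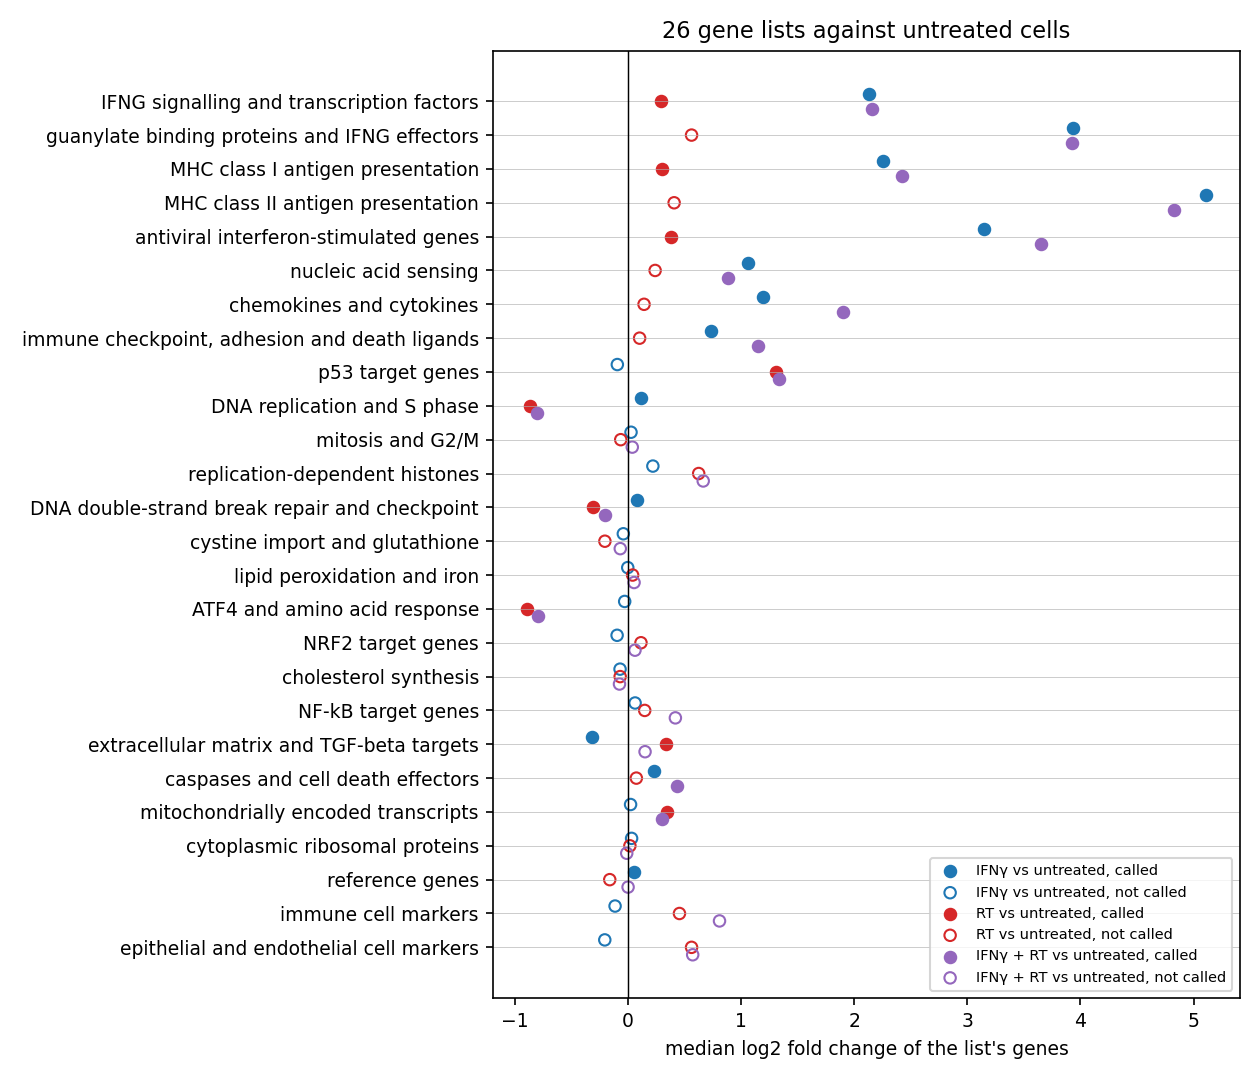
Median log2 fold change of the tested genes of each of the 26 gene lists in IFNγ-treated, irradiated and combination cells against untreated cells, with genes at 0 counts placed at their floor. Filled points mark lists called by camera, and MHC class II genes stood at 5.11 with IFNγ and p53 targets at 1.31 with radiation.

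The comparison of the combination with untreated cells measured both treatments together, and both sets of changes were present. All 22 MHC class I, all 17 guanylate binding and effector, all 32 antiviral and all 36 p53 target genes were higher (22, 17, 32 and 36 adjusted over the list alone). HLA-B rose by 4.98 ± 0.109 (SE, n = 3), GBP4 by 8.59 ± 0.42, BST2 by 8.41 ± 0.219 and FDXR by 2.65 ± 0.0725. IDO1 was at least 1540-fold higher, CXCL9 at least 205-fold, APOL4 at least 129-fold, C4B at least 117-fold and HLA-DOA at least 76.4-fold. GBP5 rose by 10.15 ± 0.467, and by 10.98 without untreated replicate 3.

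CHAC1 (-3.5 ± 0.249), FAM111B (-3.13 ± 0.0888), MCM6 (-2.68 ± 0.0521), SLC1A4 (-2.65 ± 0.14) and the secreted proteoglycan ESM1 (-2.54 ± 0.153) fell. SLC7A11 fell to 14.1 ± 1.41 CPM from 108 ± 9.78 CPM (SD, n = 3), a log2 fold change of -2.94 ± 0.0782 with an adjusted p of 8.79e-29. SLC3A2 fell by 1.49 ± 0.0463. Of 29 ATF4 and amino acid genes 24 fell and 4 rose (24 and 4 adjusted over the list alone), and ATF3 was among the higher ones at 2.45 ± 0.107. Of 40 replication genes 35 fell and 1 rose (35 and 1 adjusted over the list alone), with E2F1 at -2.14 ± 0.0866 and PCNA at 0.97 ± 0.0327. Of 33 break repair genes 19 fell and 4 rose (19 and 4 adjusted over the list alone), with EXO1 at -0.86 ± 0.0606 and ATM at 0.42 ± 0.0453.

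Of 22 IFNγ signalling genes 20 rose (20 adjusted over the list alone), with BATF2 at 5.62 ± 0.175 and TRIM22 at 4.04 ± 0.0601, and 14 of 15 MHC class II genes rose (14 adjusted over the list alone), with CD74 at 7.45 ± 0.307. IRF1 (4.68 ± 0.171), B2M (2.18 ± 0.0294), CIITA (4.67 ± 0.106) and JAK2 (0.65 ± 0.119) rose. CD274, at 34.0 ± 3.22 CPM, did not differ measurably from untreated cells (-0.05 ± 0.0755, not called). Nucleic acid sensing genes (12 of 13 higher) included AIM2 (4.17 ± 0.103) and TLR3 (3.76 ± 0.125). Chemokines and cytokines (11 higher and 3 lower of 15) included IL32 (5.61 ± 0.16), CXCL8 (-2.49 ± 0.0953) and CXCL10, at least 23.9-fold higher. Checkpoint, adhesion and death ligands (14 and 3 of 19) included ICAM1 (6.56 ± 0.395) and the death ligand TNFSF10 (5.54 ± 0.337), and caspases and death effectors (18 and 4 of 23) included CASP1 (4.02 ± 0.104) and BCL2 (-1.34 ± 0.115). These 4 lists were called and kept the same counts adjusted over the list alone.

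CDKN1A (2.40 ± 0.0373), MDM2 (2.24 ± 0.0326), GDF15 (2.57 ± 0.0414), IL6 (2.37 ± 0.232), ATM, IFNGR1 (0.24 ± 0.0716), JAK1 (0.17 ± 0.0369) and CCNB1 (0.20 ± 0.0333) were higher. MKI67 (-0.42 ± 0.0285) and ACSL4 (-0.16 ± 0.0447) were lower. GPX4 (-0.01 ± 0.0498) and IFNGR2 (-0.06 ± 0.0624) were not called, and IFNB1 stayed within the floor. All 8 mitochondrial transcripts were higher (8 adjusted over the list alone), led by MT-CYB (0.39 ± 0.0258) and MT-CO2 (0.37 ± 0.0242), with an adjusted p = 0.242 with an estimated correlation. In total 7550 genes were called (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 3752 higher and 3798 lower, with 726 higher and 206 lower by at least 2-fold. Of 26 lists 14 were called, and 13 with an estimated correlation.

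The comparison of the combination with IFNγ alone gave the effect of radiation in IFNγ-treated cells. Genes that had moved with radiation alone moved again: p53 targets were higher in 35 of 36 cases (35 adjusted over the list alone), with FDXR at 2.93 ± 0.0757 and BTG2 at 2.78 ± 0.0784. Replication genes were lower in 36 and higher in 1 of 40 (38 and 1 adjusted over the list alone), with MCM6 at -2.81 ± 0.0516 and PCNA at 0.81 ± 0.0324. Amino acid response genes were lower in 23 and higher in 4 of 29 (24 and 4 adjusted over the list alone), and ASNS fell from 110 ± 1.92 to 19.6 ± 0.536 CPM (-2.48 ± 0.0578). Break repair genes were lower in 25 and higher in 3 of 33 (25 and 3 adjusted over the list alone), with EXO1 at -0.97 ± 0.0599 and NBN at -0.68 ± 0.0393.

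NECTIN4 rose by 3.81 ± 0.101, MEGF6 by 3.72 ± 0.237, HRNR by 3.23 ± 0.197, the sulfatase SULF2 by 3.22 ± 0.32, FAM212B by 3.07 ± 0.158 and the lysosomal fucosidase FUCA1 by 3.0 ± 0.132. CHAC1 (-3.55 ± 0.247), FAM111B (-3.28 ± 0.0872), H1F0 (-2.74 ± 0.0445) and WDR76 (-2.58 ± 0.0859) fell. SLC7A11 fell from 78.3 ± 6 to 14.1 ± 1.41 CPM (SD, n = 3), a log2 fold change of -2.48 ± 0.0824, and SLC3A2 fell by 1.37 ± 0.0468. CDKN1A (2.70 ± 0.0384), MDM2 (2.19 ± 0.0325), GDF15 (2.72 ± 0.0421), IL6 (1.16 ± 0.192), GPX4 (0.27 ± 0.0515), ATM (0.32 ± 0.0449), IFNGR1 (0.39 ± 0.0733), CCNB1 (0.15 ± 0.0332) and CXCL9 (1.34 ± 0.315) rose. CD274 (-0.78 ± 0.0689), CIITA (-0.38 ± 0.0563), MKI67 (-0.53 ± 0.0285) and ACSL4 (-0.28 ± 0.0444) fell.

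JAK1 (0.10 ± 0.0368) was called, but not without IFNγ replicate 2 (0.09), IFNγ replicate 3 (0.09) or combination replicate 2 (0.09). IRF1 (-0.13 ± 0.0973) and CXCL10 (-0.54 ± 0.476) were not called, and were called without combination replicate 3 (-0.23 and -1.11). IDO1 (-0.30 ± 0.263), B2M (0.02 ± 0.0271), IFNGR2 (0.01 ± 0.0631) and JAK2 (0.02 ± 0.11) were not called.

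Extracellular matrix genes were higher in 20 and lower in 3 of 29 (22 and 3 adjusted over the list alone), with ACTA2 at 2.46 ± 0.0885, and an adjusted p = 0.203 with an estimated correlation. Mitochondrial transcripts were higher in 7 of 8 (7 adjusted over the list alone), led by MT-CO2 (0.42 ± 0.0242) and MT-ND6 (0.34 ± 0.0465), with an adjusted p = 0.419 with an estimated correlation. Reference genes were lower in 10 and higher in 2 of 16 (10 and 2 adjusted over the list alone), with TFRC at -0.80 ± 0.0279 and SDHA at 0.43 ± 0.0379, and an adjusted p = 0.292 with an estimated correlation. MHC class II genes (2 higher and 11 lower of 15, 3 and 12 adjusted over the list alone) and antiviral genes (17 and 1 of 32, 17 and 1 adjusted over the list alone) were not called as lists. The antiviral list (adjusted p = 0.0949) was called as higher without IFNγ replicate 1 (0.0274), combination replicate 1 (0.0375) or combination replicate 2 (0.0422). In total 7380 genes were called (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 3685 higher and 3695 lower, with 589 higher and 143 lower by at least 2-fold. Of 26 lists 7 were called, and 4 with an estimated correlation.

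The comparison of the combination with radiation alone gave the effect of IFNγ in irradiated cells. MHC class I genes rose in 21 of 22 cases (21 adjusted over the list alone), with PSMB9 at 4.46 ± 0.0753 and HLA-B at 4.10 ± 0.0988, and antiviral genes in 31 of 32 (31 adjusted over the list alone). BST2 rose from 0.133 ± 0.0588 to 58.5 ± 6.81 CPM (8.66 ± 0.227), and XAF1 by 8.08 ± 0.474 (9.32 without irradiated replicate 1). IDO1 rose by 8.75 ± 0.797 and GBP5 by 8.35 ± 0.394; without irradiated replicate 2, which held most of their few counts in irradiated cells, the values were 10.38 and 10.22. CXCL9 and IFI44L had 1 count each over the irradiated libraries, with ratios of 596 (95% interval 107 to 23600) and 425 (75.9 to 16800).

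SLC7A11 fell from 33.6 ± 2.03 to 14.1 ± 1.41 CPM (SD, n = 3), a log2 fold change of -1.26 ± 0.0967 with an adjusted p of 1.34e-13. The cyclic GMP phosphodiesterase PDE5A fell by 1.32 ± 0.0817, LONRF2 by 1.29 ± 0.137, ZNF469 by 1.24 ± 0.161, MTURN by 1.15 ± 0.116 and the cytokine IL1A by 1.11 ± 0.171 on the log2 scale. SLC3A2 (-0.20 ± 0.053) and GPX4 (-0.21 ± 0.049) were lower. ACSL4 (-0.01 ± 0.0453), ATM (-0.01 ± 0.0437), CDKN1A (-0.06 ± 0.0318), IFNGR1 (0.11 ± 0.0707) and IFNGR2 (-0.11 ± 0.0624) were not called. IRF1 (4.34 ± 0.165), CD274 (0.69 ± 0.0843), B2M (1.80 ± 0.0288), JAK2 (0.78 ± 0.123), GDF15 (0.18 ± 0.0347), CIITA (5.01 ± 0.112), IL6 (0.84 ± 0.183), MKI67 (0.15 ± 0.029) and CCNB1 (0.20 ± 0.0334) rose, and CXCL10 was at least 23.2-fold higher. MDM2 was at 0.10 ± 0.0297 (not called without irradiated replicate 3, at 0.08, or combination replicate 3, at 0.08). JAK1 was at -0.10 ± 0.0363 and lost its call with any of the 6 libraries left out (-0.11 to -0.09).

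IFNγ signalling genes rose in 18 and fell in 1 of 22 cases, guanylate binding and effector genes rose in 16 of 17, MHC class II genes in 14 of 15 and nucleic acid sensing genes in 10 of 13. BATF2 rose by 4.84 ± 0.159, GBP4 by 7.80 ± 0.389, CD74 by 6.52 ± 0.277 and AIM2 by 4.09 ± 0.103. Adjusted over the list alone the counts were 18 and 1, 16, 15 and 10. Chemokines and cytokines rose in 9 and fell in 3 of 15 (9 and 4 adjusted over the list alone), with IL32 at 3.14 ± 0.112 and CXCL8 at -0.90 ± 0.119. Checkpoint, adhesion and death ligands rose in 12 and fell in 3 of 19 (12 and 3 adjusted over the list alone), with ICAM1 at 5.57 ± 0.351 and the stress ligand MICA at -0.32 ± 0.101. Caspases and death effectors rose in 13 and fell in 1 of 23 (14 and 1 adjusted over the list alone), with CASP1 at 2.62 ± 0.0849 and BCL2 at -0.49 ± 0.131.

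Mitotic genes rose in 21 of 34 cases and fell in 0 (23 and 0 adjusted over the list alone), by small amounts: HMMR by 0.26 ± 0.0385 and TOP2A by 0.22 ± 0.0277. Replication genes rose in 13 and fell in 1 of 40 (13 and 1 adjusted over the list alone), with PCNA at 0.51 ± 0.0318 and GINS4 at -0.28 ± 0.073, and an adjusted p = 0.114 with an estimated correlation. Extracellular matrix genes fell in 19 and rose in 3 of 29 (20 and 4 adjusted over the list alone), with CTGF at -1.08 ± 0.0438 and TNC at 1.34 ± 0.0784, and an adjusted p = 0.0737 with an estimated correlation. Reference genes, again led by B2M, were higher in 6 and lower in 2 of 16 (6 and 2 adjusted over the list alone). Their adjusted p = 0.235 with an estimated correlation, and their call ended without TMM (adjusted p = 0.0882), without irradiated replicate 2 (0.0686) and without combination replicate 1 (0.0745).

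In total 3270 genes were called (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 1761 higher and 1509 lower, with 299 higher and 42 lower by at least 2-fold. DESeq2 called 2129. The share of called genes that were higher was 53.9%, and 38% with library totals in place of TMM. Of 26 lists 13 were called, and 10 with an estimated correlation. Camera on ranks called 12, without the chemokine and reference lists and with break repair. Across all tested genes the IFNγ effects with and without radiation, which share no library, had a Pearson correlation of 0.9 and a Spearman correlation of 0.598; genes are not independent replicates. In both contrasts 1192 genes were higher, where independent lists would share 264.9, and 863 were lower, where 212.8 would be shared. The corresponding radiation effects had correlations of 0.863 and 0.861, with 2810 genes higher in both (1027 for independent lists) and 2891 lower (1041).

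**Figure D3:**
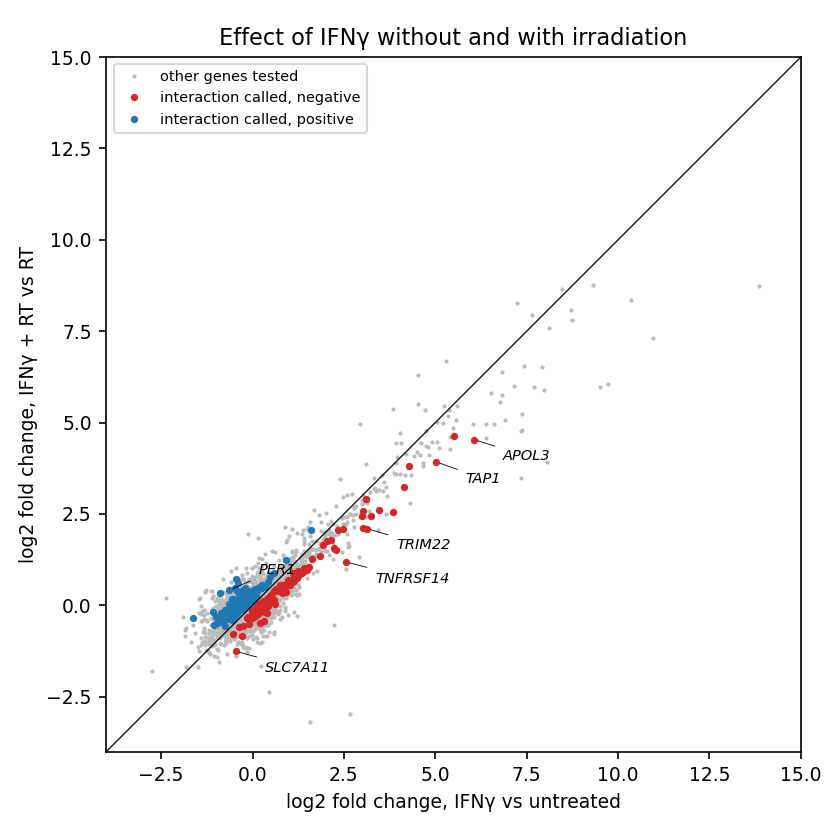
Log2 fold change of each of the 12160 tested genes with IFNγ in unirradiated cells (x axis, IFNγ against untreated) and in irradiated cells (y axis, combination against radiation), with the 289 genes called for the interaction coloured and the line of equal effects drawn. Most genes lie near the line, but on these axes small changes cannot be told apart. Across genes the Pearson correlation was 0.9 and the Spearman correlation 0.598.

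The interaction asked whether both treatments together differed from the sum of their separate log2 effects. SLC7A11 lay below that sum: the product of the separate effects gives 24.4 CPM, and 14.1 ± 1.41 CPM (SD, n = 3) was measured, an interaction term of -0.79 ± 0.114 (log2 ± SE) with an adjusted p of 2.29e-05. This departure depends on the scale, since the sum of the separate changes in CPM gives 3.85, below the level measured. Several interferon-induced genes fell short of the product. APOL3 was at 58.7 ± 1.77 CPM where the product gives 172 (-1.52 ± 0.308), the peptide transporter TAP1 at 484 ± 42 CPM where it gives 1040 (-1.11 ± 0.2), TRIM22 at 374 ± 28.7 where it gives 766 (-1.03 ± 0.0863) and UBE2L6, which conjugates ISG15, at 259 ± 9.46 where it gives 488 (-0.91 ± 0.0909). TNFRSF14 (-1.37 ± 0.179) and the sodium channel SCN9A (-1.27 ± 0.347) also had negative terms. The sum of the separate changes in CPM, which was not tested, gives 60.1 for APOL3, 552 for TAP1 and 301 for UBE2L6, nearer to the measured levels. It gives 265 for TRIM22 and 29.6 for TNFRSF14 (measured at 32.2 ± 3.51), below the measured levels. SCN9A, measured at 9.98 ± 1.7 CPM, lay below both the sum (15.9) and the product (24.4).

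Positive terms were found for the clock gene PER1 (1.05 ± 0.187), FAAP24 (0.99 ± 0.268), HHEX (0.94 ± 0.262), SEMA3B (0.89 ± 0.253), ISM1 (0.81 ± 0.219) and WBSCR27 (0.74 ± 0.196). PER1 stood at 9.43 ± 0.645 CPM in untreated, 6.03 ± 0.875 in IFNγ-treated, 7.11 ± 0.92 in irradiated and 9.5 ± 0.4 in combination cells (SD, n = 3). CDKN1A (0.25 ± 0.0546) and GDF15 (0.32 ± 0.0611) had positive terms, and B2M (-0.36 ± 0.0404) a negative one.

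No interaction was called for SLC3A2 (-0.09 ± 0.0667), GPX4 (0.07 ± 0.0711), ACSL4 (-0.13 ± 0.0631), ATM (-0.11 ± 0.064), MDM2 (0.04 ± 0.0453), IRF1 (-0.47 ± 0.33), CD274 (-0.04 ± 0.11), IFNGR1 (0.26 ± 0.104), IFNGR2 (-0.03 ± 0.0885), JAK1 (-0.17 ± 0.0521), JAK2 (0.15 ± 0.174), CIITA (-0.04 ± 0.242), MKI67 (0.04 ± 0.0404), CCNB1 (0.15 ± 0.0474, called at 0.18 without combination replicate 3) or IL6 (-0.38 ± 0.338). IDO1, CXCL9, CXCL10 and IFNB1 had too few counts without IFNγ for the term to be estimated.

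By list, 8 of 22 IFNγ signalling genes (11, and 1 positive, adjusted over the list alone), 3 of 17 guanylate binding and effector genes (4 adjusted over the list alone) and 6 of 22 MHC class I genes (10 adjusted over the list alone) had negative terms. Examples are IRF9 (-0.89 ± 0.131), IFI16 (-0.36 ± 0.0708) and the immunoproteasome subunit PSMB8 (-0.55 ± 0.0833). The lists of MHC class II (0 of 15 called, 1 adjusted over the list alone, median -0.80, and -0.32 without irradiated replicate 2), amino acid response (2 negative of 29, 3 adjusted over the list alone), mitosis (1 positive of 34, 6 adjusted over the list alone) and ribosomal proteins (2 negative of 40, 4 adjusted over the list alone) were called too. The members called in the amino acid list were SLC7A11 and ASNS (-0.35 ± 0.0901), in mitosis TOP2A (0.15 ± 0.0396), and among ribosomal proteins RPL7 (-0.15 ± 0.0411) and RPS24 (-0.14 ± 0.0397). Without irradiated replicate 2, 0 members of the mitosis and ribosomal lists were called in edgeR, and 7 signalling, 2 guanylate binding and effector, and 4 MHC class I genes had negative terms. The call of the amino acid list ended without untreated replicate 2 (adjusted p = 0.0733), IFNγ replicate 2 (0.0631) or combination replicate 1 (0.0522). It also ended with camera on ranks. The antiviral list was called as lower without IFNγ replicate 3 (0.0246) or combination replicate 3 (0.00117). All 7 list calls were lost with an estimated correlation: signalling, MHC class I and mitosis had an adjusted p = 0.291, guanylate binding, MHC class II and amino acid response an adjusted p = 0.331, and ribosomal proteins an adjusted p = 0.674 with an estimated correlation.

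In total 289 genes were called (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 168 with positive and 121 with negative terms, 4 and 5 of them at least 2-fold. Of the positive terms, 116 were at genes called lower with IFNγ alone, 14 at genes called higher and 38 at genes not called. Of the negative terms, these counts were 8, 89 and 24. A positive term can thus mean a smaller decrease with IFNγ. The share of positive terms was 58.1%, and 69.4% with library totals in place of TMM. DESeq2 called 147 genes, 71 positive and 76 negative (48.3% positive), so the majority turned. In edgeR 161 were called without irradiated replicate 2 and 179 without combination replicate 2. The calls of FAAP24, HHEX, SEMA3B, ISM1, WBSCR27, SCN9A and TAP1 ended in 5 to 9 of the 12 fits that left out a library.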

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

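The tests below on carry-over, on scaling and on the other members of the amino acid list were chosen only after the results were seen. So were the count of interferon calls that remained without irradiated replicate 2 and the correlation of regroupings with the treatments. Fits that left out each library in turn, the selection of genes by their fold in irradiated cells and the splits of the libraries were planned.

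The effect of IFNγ differed between irradiated and unirradiated cells for 16 named genes, by the test of the interaction term itself (edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 12 libraries). The log2 effect in irradiated cells was higher for PER1 (1.05), FAAP24 (0.99), HHEX (0.94), SEMA3B (0.89), ISM1 (0.81), WBSCR27 (0.74), GDF15 (0.32) and CDKN1A (0.25). It was lower for APOL3 (-1.52), TNFRSF14 (-1.37), SCN9A (-1.27), TAP1 (-1.11), TRIM22 (-1.03), UBE2L6 (-0.91), SLC7A11 (-0.79) and B2M (-0.36). PER1, APOL3, TNFRSF14, TRIM22, UBE2L6, SLC7A11, CDKN1A, GDF15 and B2M kept their calls in each of the 12 fits that left out 1 library. FAAP24 lost its call in 7 of these fits (terms over the 12 fits 0.848 to 1.171), HHEX in 9 (0.832 to 1.044), SEMA3B in 9 (0.793 to 0.985), ISM1 in 8 (0.719 to 0.927), WBSCR27 in 5 (0.502 to 0.883), SCN9A in 7 (-1.544 to -1.085) and TAP1 in 7 (-1.178 to -1.007).

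The first pattern is the higher level of some interferon-related genes in irradiated cells. Of 108 tested genes of 5 interferon lists 45 were called higher, 4 lower and 59 not called. Over all 12160 tested genes, 3389 were called higher and 3427 lower. Signalling (12 of 22) and MHC class I genes (15 of 22) exceeded that share of higher calls. Antiviral (10 of 32) and guanylate binding genes (5 of 17) lay near it, and MHC class II genes (3 of 15) below it. The median log2 fold change was 0.379 over the 108 and 0.453 ± 0.0625 (SE over genes) over the 45. Of these lists 3 were called, but not with an estimated correlation (adjusted p = 0.278, 0.278 and 0.565). Irradiated replicate 2 may hold reads from IFNγ-treated libraries: its counts of 10 near-silent marker genes other than GBP5 were 0.858 times (95% interval 0.515 to 1.39) the sum predicted from GBP5 alone, 25 counts against 29.1, but it also held 21 genes with more counts than in the other 11 libraries together, led by HBB (304), whose source was not tested. CD74, which was not among these markers, had 98 counts in irradiated replicate 2 against 18 and 21 in irradiated replicates 1 and 3. It had 5544 to 6312 counts in IFNγ libraries. The share estimated for irradiated replicate 2, 0.662% of such counts, is less than its excess of CD74 reads. It therefore does not account for all of them, and the source of the rest was not tested. After subtraction of the estimated share from each library without IFNγ, 100% of the 45 calls remained, so carry-over of the estimated size does not account for these calls. Without irradiated replicate 2, 40 remained, and whether other material in that library contributed to the 5 that ended, ISG15 (0.77), CTSS (1.44), HLA-DRB5 (2.35), IFIT3 (1.00) and TAPBPL (0.31), is left open. The lowest median over the other scalings was 0.453, but the genes were chosen by their calls and the scalings moved the median of all genes by at most 0.0199, so this says little about scaling beyond those run.

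The second pattern is a smaller fold change with IFNγ in irradiated cells, a median interaction term of -0.23 ± 0.0258 over the 310 genes raised at least 2-fold by IFNγ alone. After subtraction of the estimated carry-over the median was -0.222. When the genes were instead chosen by their fold in irradiated cells, the median was -0.142 ± 0.0256 over 299 genes, 192 of them negative. Both stayed below 0 by more than 2 standard errors over genes, which are not independent of each other. Genes lowered by IFNγ alone also mostly had terms opposed to its effect, 116 positive and 8 negative among called terms. These counts share the untreated and IFNγ libraries with the term, so selection can favour opposed signs. The term is also the effect of radiation in IFNγ-treated cells minus its effect in untreated cells. This pattern is therefore not independent of the first, and a smaller fold need not mean a lower level with IFNγ. In radiation against untreated, list medians were 0.295 (signalling), 0.563 (guanylate binding), 0.298 (MHC class I), 0.409 (MHC class II) and 0.384 (antiviral). In combination against IFNγ they were 0.043, -0.081, 0.071, -0.464 and 0.202. Part of this rests on irradiated replicate 2. Without it the guanylate binding median with radiation was lower and the median interaction term of MHC class II was smaller in size, as given in the Results. The median term of the 310 genes was not computed without that library. No biological explanation of the difference was tested.

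The third pattern is SLC7A11, whose level in the combination was below the product of the separate effects. The term closest to 0 over the other scalings was -0.777 ± 0.116. The other 28 members of the ATF4 and amino acid list had a median term of -0.069 ± 0.0339 with 1 of them called, ASNS, so a shift shared evenly by that list does not reach the value of SLC7A11. A joint effect of both treatments on SLC7A11 in particular may remain as a hypothesis on the log2 scale only, since 14.1 CPM lies below the product (24.4) and above the sum of the separate changes (3.85). SLC7A11 and the interaction test were fixed beforehand. The comparison with the other list members was chosen and run on the same data.

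For each pairwise comparison the 6 libraries allow 10 splits, too few for a share under 0.05. In fits of these 6 libraries alone, 1 of 10 splits, the real one, called as many genes in each comparison. The real splits called 3240 (IFNγ against untreated), 6729 (radiation against untreated), 7365 (combination against untreated), 7345 (combination against IFNγ) and 3581 genes (combination against radiation). The highest other split called 0 genes in edgeR, with 558, 120, 109, 84 and 238 genes at an unadjusted p under 0.05, against 4359, 7260, 7746, 7704 and 4632 in the real splits. Each other split mixes the 2 groups, so the effect of treatment widens its spread. These gene counts therefore say little about chance. For gene lists, in the same order, the real splits called 13, 9, 15, 9 and 13 lists, the highest other split called 11, 9, 16, 13 and 11, and 1, 3, 2, 6 and 1 of 10 splits called as many.

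For the interaction, 1 of 100 regroupings, the real one, called as many genes as the 289 found, and the highest other called 0 in edgeR. Regroupings mix treated and untreated libraries, so the large effects of treatment widen their spread and this count says little about chance. At an unadjusted p under 0.05, 12 of the 99 others called more genes than the 1788 of the real grouping, up to 4879. In each of these 12 the larger absolute correlation of the 2 sides of the contrast with IFNγ or with radiation was 0.667, so they partly followed the treatments. In the real grouping and in 17 others this correlation was 0. These 17 had 23 to 87 genes at an unadjusted p under 0.05, where 5% of the tested genes would be 608, so they do not stand for a grouping without effect either. They are also too few, since the smallest share they allow is 0.0556. Whether chance can be excluded for the 289 genes is left open. For the 7 interaction lists, 64 of 100 regroupings called as many, with 15 as the highest other. Each other regrouping that called as many had a correlation of 0.333 or 0.667 with a treatment, and the 17 without one called 0 to 2 lists, so whether chance can be excluded for the list calls is left open as well.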

How the results depend on the processing

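Subtraction of the carry-over was chosen only after the data were seen, and the other alternatives in this section were planned. The alternatives covered values of genes named as largest changes or fixed by name, with more than 3 counts in each compared group. Of these 172 gene values, 137 kept their direction and call in every alternative. Genes named only as list members, and values at the floor, did not enter. For the interaction, 289 genes became 120 at an adjusted p under 0.01 and 147 in DESeq2, and 161 to 332 with 1 library left out (161 without irradiated replicate 2, 179 without combination replicate 2). Interaction genes with at least 2-fold terms numbered 4 at an adjusted p under 0.01, 4 in DESeq2 and 3 to 13 with 1 library left out. DESeq2 called fewer genes than edgeR in every pairwise comparison. It called 2366 in IFNγ against untreated, 5598 in radiation against untreated and 6277 in combination against untreated. It called 6039 in combination against IFNγ and 2129 in combination against radiation. With 1 library left out, the other counts ran from 2878 to 3306 (IFNγ against untreated), 6334 to 6592 (radiation against untreated), 7008 to 7315 (combination against untreated), 6828 to 7039 (combination against IFNγ) and 2669 to 3005 (combination against radiation). Camera with an estimated correlation called 4 lists in radiation against untreated, 4 in combination against IFNγ and 0 in the interaction, where 8 lists had an unadjusted p under 0.05 with the preset correlation. Fry, which tests each list without the other genes as background, called 23, 25, 19 and 4 lists in radiation against untreated, combination against untreated, combination against IFNγ and the interaction. With 1 library left out, further lists gained a call: immune cell markers in combination against untreated without untreated replicate 3 (adjusted p = 0.0462) and in combination against IFNγ without IFNγ replicate 3 (0.0346), break repair in combination against radiation without irradiated replicate 2 (0.0331), combination replicate 2 (0.0498) or combination replicate 3 (0.0429), ribosomal proteins there without combination replicate 1 (0.0289), and in the interaction mitochondrial transcripts without IFNγ replicate 2 (0.0164) and cholesterol synthesis without irradiated replicate 3 (0.0457) or combination replicate 3 (0.0465). Where no construction of the alternative is given, the cause was not tested. Changes of about 0.25 in log2 were recovered in 40% of simulated genes at this depth and 24% for the interaction.

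Directions turned for genes that were not called. CCNB1 in radiation against untreated became 0.005 with DESeq2 size factors, 0.018 with library totals, 0.003 in DESeq2 and 0.001 in a fit of 2 groups, and ran from -0.02 to 0.018 with 1 library left out. With library totals MDM2 and CCNB1 in IFNγ against untreated became -0.001 and -0.01. CIITA in the interaction became 0.112 after subtraction of the carry-over. With 1 library left out, GPX4 (-0.05 to 0.03) and CD274 (-0.128 to 0.03) turned in combination against untreated, B2M (-0.004 to 0.053), IFNGR2 (-0.055 to 0.053) and JAK2 (-0.124 to 0.12) in combination against IFNγ, and ACSL4 (-0.045 to 0.023) and ATM (-0.057 to 0.036) in combination against radiation. In the interaction CD274 (-0.124 to 0.068), CIITA (-0.145 to 0.119) and IFNGR2 (-0.097 to 0.01) turned.

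Some calls of single genes also changed with 1 setting. With library totals, ACSL4 (0.062) and MKI67 (0.05) lost and IFNGR1 (-0.207) gained a call in IFNγ against untreated, MDM2 (0.058) lost and CDKN1A (-0.1) gained a call in combination against radiation, and CCNB1 (0.169) gained an interaction call. Without a filter on low counts, SLC3A2 (-0.105) lost and ATM (0.116) gained a call in IFNγ against untreated, and JAK1 lost its calls in combination against IFNγ (0.086) and against radiation (-0.094). DESeq2 did not call JAK1 in combination against radiation (-0.102). Fits of 2 groups called IRF1 in radiation against untreated (0.345). Limma-voom did not call HHEX (0.92), SEMA3B (0.88), WBSCR27 (0.7) or TAP1 (-1.103) for the interaction. The cause was not tested.

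The labels do not pair libraries by replicate number. Residuals of libraries with the same number correlated from -0.0711 to 0.0537 (18 pairs) and of those with different numbers from -0.101 to 0.0946 (36 pairs). With the number as a block, 3525, 6804, 7541, 7347, 3262 and 276 genes and 13, 9, 14, 7, 13 and 7 lists were called in the order of the report. TAP1 lost its interaction call (-1.10, adjusted p of 0.074), and the block changed no other call of a named gene. Among lists in combination against radiation, reference genes lost and DNA break repair gained a call with the block.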

Other observations

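The families in the next paragraph were chosen after their values were seen, and they were not tested as sets. Butyrophilins, semaphorins and plexins, and circadian genes were looked at too. With radiation 2 of 5, 12 of 26 and 3 of 13 rose, and 0, 4 and 4 fell. The test of gene span was planned.

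Complement genes rose with IFNγ in 12 of 14 cases and fell in 1, with C1S at 5.50 ± 0.0959 (log2 fold change ± SE, n = 3) and C1R at 5.38 ± 0.115. They also rose with radiation in 6 and fell in 1 of 14 cases, with C3 at 3.89 ± 0.684. Of all 12160 tested genes, 1829 rose with IFNγ and 3389 with radiation. All 6 tested APOBEC3 cytidine deaminases rose with radiation and 5 rose with IFNγ, and APOBEC3G was at 2.2 ± 0.129 with IFNγ, 1.61 ± 0.143 with radiation and 3.82 ± 0.102 with both. Lysosomal hydrolases rose with radiation in 18 of 21 cases, FUCA1 by 2.87 ± 0.119 and NEU1 by 1.11 ± 0.0619, while with IFNγ 2 rose and 5 fell.

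Irradiated replicate 2 held an estimated 0.662% of the mean IFNγ profile, where the other untreated and irradiated libraries held 0.0434% to 0.196%. In the same library 21 genes had at least 10 counts and more counts than the other 11 libraries together, 1129 counts or 0.0117% of its total, led by HBB (304), IGF2 (177), DLK1 (161), HBA2 (81), DBH (71) and JCHAIN (63). The other libraries had 0 such genes. In untreated replicate 1, 390 genes had 1 to 9 counts and none elsewhere, against 22 to 142 genes in the other libraries.

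It was tested whether long genes were lower after radiation, as lasting blocks to transcription might produce. Genes in the longest quintile by span (at least 103 kb) had a median log2 fold change 0.078 ± 0.0129 above that of the shortest quintile (at most 11 kb) in radiation against untreated, and 0.058 ± 0.0122 above it in combination against IFNγ, over 12154 genes. The hypothesis predicted a negative difference and was not met.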
